A study of Mus musculus with 12 samples.

How the data were processed

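Gene expression was measured in the spleen of C57BL6 mice with 12 two-colour Agilent arrays, 4 for each of 3 groups: mice with the V235fs form of TREX1 knocked in, mice with the D272fs form knocked in, and control mice. Per the labels, RNA was isolated with Trizol, spleen cDNA was labelled with Cy3 and a universal reference RNA with Cy5, on every array alike, so no dye swap was made. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the 4 samples of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

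The deposited scanner files give, for each spot, the mean pixel intensity of both dyes and the median intensity of the local background, read with Agilent Feature Extraction 11.5.1.1 per the file headers. They also give processed intensities and a log10 ratio of Cy5 over Cy3 that Feature Extraction had background-subtracted and dye-normalised, per the file headers. The authors' value table held the same log10 ratios, rounded, for 36233 features: each column lay within 0.005 of its scanner file, so its scale and direction were settled by that comparison. Its column medians lay between 0 and 0.0035, and no further centring between arrays was found.

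Each array carried 37558 spots, of which 1417 were control spots and 184 were other spots that were left out, which left 35957 spots of 35852 mouse probes. The files do not pair the probe IDs with genes: the gene name column repeated the probe ID for all 36141 non-control spots, and the gene table used here holds no probe sequences. Results are therefore given per probe, by ID. The interferon gene list, the other pathway lists, the cell type markers and the level of Trex1 that had been planned need gene names and were not run, nor was the choice of 1 probe per gene.

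Background was corrected with limma 3.58.1 in R 4.3.3 by the normexp method with an offset of 50, on mean signals and median backgrounds, and each array was normalised by loess with control spots at weight 0. The log2 ratio of spleen over reference was used throughout. Spots that Feature Extraction marked as outliers (69 over the 12 arrays) were set to missing and spots of 1 probe were averaged. A probe was tested if its Cy3 signal was well above background on at least 4 of the 12 arrays and it had at least 2 values in each group, which left 26502 probes. A linear model with 1 mean per group was fitted over all 12 arrays with limma, with empirical Bayes moderation (9 residual and 2.62 prior degrees of freedom). A probe was called changed at a Benjamini-Hochberg adjusted p under 0.05, over the probes tested in that comparison. Where a probe was not well above background on the arrays of a group, the size of its change is given as uncertain.

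The test, the samples in it, the filter, most alternatives and the rule for naming probes were fixed before the data were examined. The rule was to name, in each direction, the called probes with the largest change and no overlap between the 4 arrays of one group and the 4 of the other. Because the probes have no gene names, at most 2 that rose and 2 that fell are named per comparison, and the parts of the rule that name uncalled probes, list members or the probes shared by both knock-ins were not applied. Alternatives covered the background correction, the normalisation, the filter, the slide, the position on the slide, the replicate number, array weights, the variance model, the samples in the fit and each array left out. A background taken from the 153 negative control spots, scan day as a block, slide position 4 alone, and a few combinations were added after the data had been seen.

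The arrays came from 5 slides and were scanned on 3 days. All V235fs arrays lay on 1 slide and all D272fs arrays on another, while the control arrays lay on 3 further slides. All 8 knock-in arrays were scanned on 1 day and the controls on 2 other days. Slide and scan day were fitted as random blocks, but neither can be told apart from the knock-in groups. Such a block cannot remove the slide or day effect of a knock-in group, which is part of that group's mean. Calls that stay with these blocks are therefore not free of such effects. The number of arrays limits the precision. In simulated data with the spread of these arrays, the V235fs against control test on 26502 probes recovered 53.7% of probes changed 1.5-fold, 85.1% of those changed 2-fold and 100% of those changed 4-fold, and 7 of its 166 calls were unchanged probes. The simulated noise was normal and independent, with 1 spread per probe in all groups and no slide or scan day effect. These rates therefore do not cover errors from slide or day.

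The overlap and the correlation of the knock-in comparisons, which share the control arrays, were set beside 100 simulations of unchanged groups against the same controls and were recomputed with the controls split 2 and 2. Other splits of the arrays were counted in full (35 per comparison) or drawn (100 for the overlap). Probe sequences were translated in 3 frames and compared with human protein sequences written down from general knowledge after the fold changes had been seen, for the closing observations alone.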

Results

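The series profiled the spleen of mice that express mutant human TREX1, a DNA exonuclease, from a conditional knock-in. V235fs is the most frequent mutation in retinal vasculopathy with cerebral leukodystrophy (RVCL), a small-vessel disease, and D272fs was found in a case of systemic lupus erythematosus. Spleen RNA of 4 V235fs, 4 D272fs and 4 control samples was hybridised against a common reference, 1 sample per array. The labels do not say whether the control mice were wild type or carried the knock-in unexpressed. Cy3, the spleen channel, was well above background for 69.2% to 74.9% of mouse probes per array, with a median signal between 94.3 and 220 and no saturated spot. Gene names cannot be given because the files do not pair probe IDs with genes.

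Each array was compared with the other 3 of its group. The mean correlation of log ratios across probes was between 0.928 and 0.974 on 11 arrays and 0.865 on D272fs replicate 3. The background model could not be fitted well on that array: its estimated Cy3 background was −391.71 (SD 570.48), whereas its negative control spots averaged 21.9. On V235fs replicate 4 it fitted poorly too, to a smaller extent, with an estimate of −21.6 (SD 22.4) against 20.4 for the negative control spots. With a background from the negative control spots the correlation of D272fs replicate 3 was 0.963. The spread between D272fs samples (root mean square SD over probes) was 0.331 log2 units, against 0.225 in the controls and 0.193 in V235fs, and it was 0.206 in D272fs with that background.

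**Figure D1:**
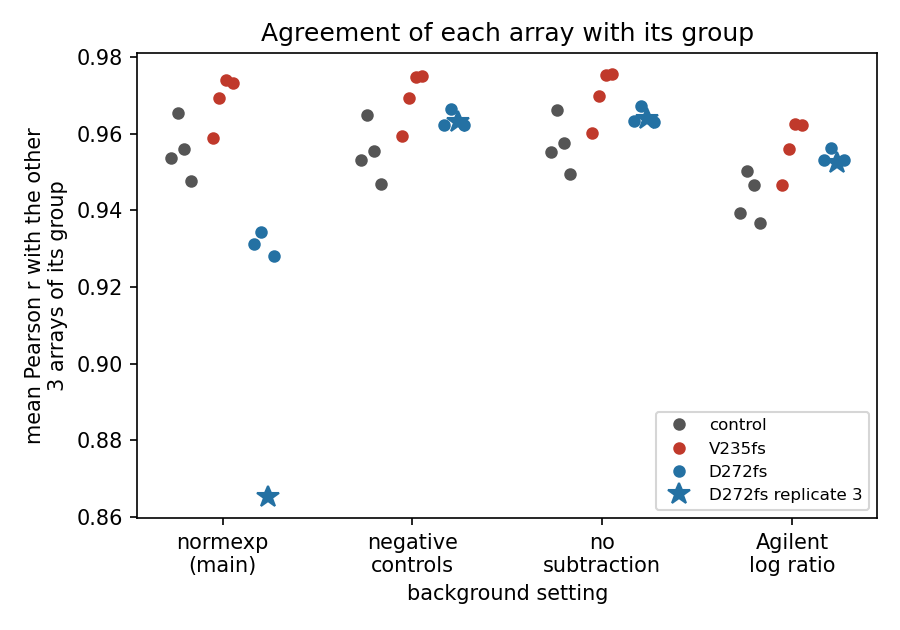
Mean Pearson correlation across probes of each array with the other 3 of its group (vertical axis) under 4 background settings (horizontal axis); each point is 1 array and the star is D272fs replicate 3. The star sits at 0.865 with the main setting and at 0.963 with a background from negative control spots.

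The first comparison asked how the V235fs spleen differed from the control spleen. Expression of 228 of the 26502 probes changed, 132 upwards and 96 downwards, and 36 of them changed at least 2-fold. Most changes were small, with a median rise of 0.64 and a median fall of −0.67 on the log2 scale. M200003525 fell: its log2 ratio was −2.16 ± 0.19 in V235fs and 1.23 ± 0.27 in control (SD, n = 4 each), a 10.5-fold lower level (log2 change −3.39, SE 0.31, limma adjusted p = 0.00113). M300001033 fell too, with log2 ratios of 0.13 ± 0.05 and 2.52 ± 0.25 (SD, n = 4 each, limma adjusted p = 1.84e-06), but was not well above background on any V235fs array, so the size of its fall is not known. Its measured log2 change, −2.39 here, was between −3.70 and −1.95 under the alternatives.

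Among the probes that rose in V235fs, M400003301 went from −0.18 ± 0.31 to 1.42 ± 0.40 (SD, n = 4 each), a log2 change of 1.61 (SE 0.27, limma adjusted p = 0.0301). M400015708 went from −1.36 ± 0.48 to 0.13 ± 0.17, a log2 change of 1.49 (SE 0.21, limma adjusted p = 0.0164). The 4 V235fs arrays did not overlap the 4 control arrays at any called probe, nor at 14.2% of all tested probes, where chance gives 2.86%.

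The count of V235fs changes moved with the setting. It was 1398 without D272fs replicate 3, 2194 with a background from negative control spots, 50 with slide as a random block, 26 with scan day as one and 7 with position on the slide as a fixed block. These blocks ended the call of M400003301, whose change stayed between 1.57 and 1.61 while its SE rose to between 0.30 and 0.34, and position ended that of M400015708 (change 1.49, SE 0.27). With the Cy3 channel alone M400003301 changed by 0.43 (SE 0.30) and was not called. Its normalised Cy3 signal averaged 13.1 in V235fs and 12.7 in control (log2), so most of its rise came from the reference channel. All 228 probes kept their call and direction without D272fs replicate 3, and M200003525 kept its call in 31 of 31 alternatives, with a log2 change between −5.32 and −2.98, and M300001033 in 30 of 30. Leaving out another array gave 710 (V235fs replicate 1), 22 (V235fs replicate 2), 17 (V235fs replicate 3 or 4), 98 (D272fs replicate 1), 141, 29, 137 or 139 (control replicates 1 to 4). Whether rises or falls were more numerous depended on the setting too: 110 probes rose and 29 fell without control replicate 4, whereas 48 rose and 89 fell without control replicate 3, 301 and 409 without V235fs replicate 1, 464 and 547 in a fit of only the 2 groups, and 0 and 6 with median centring.

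**Figure D2:**
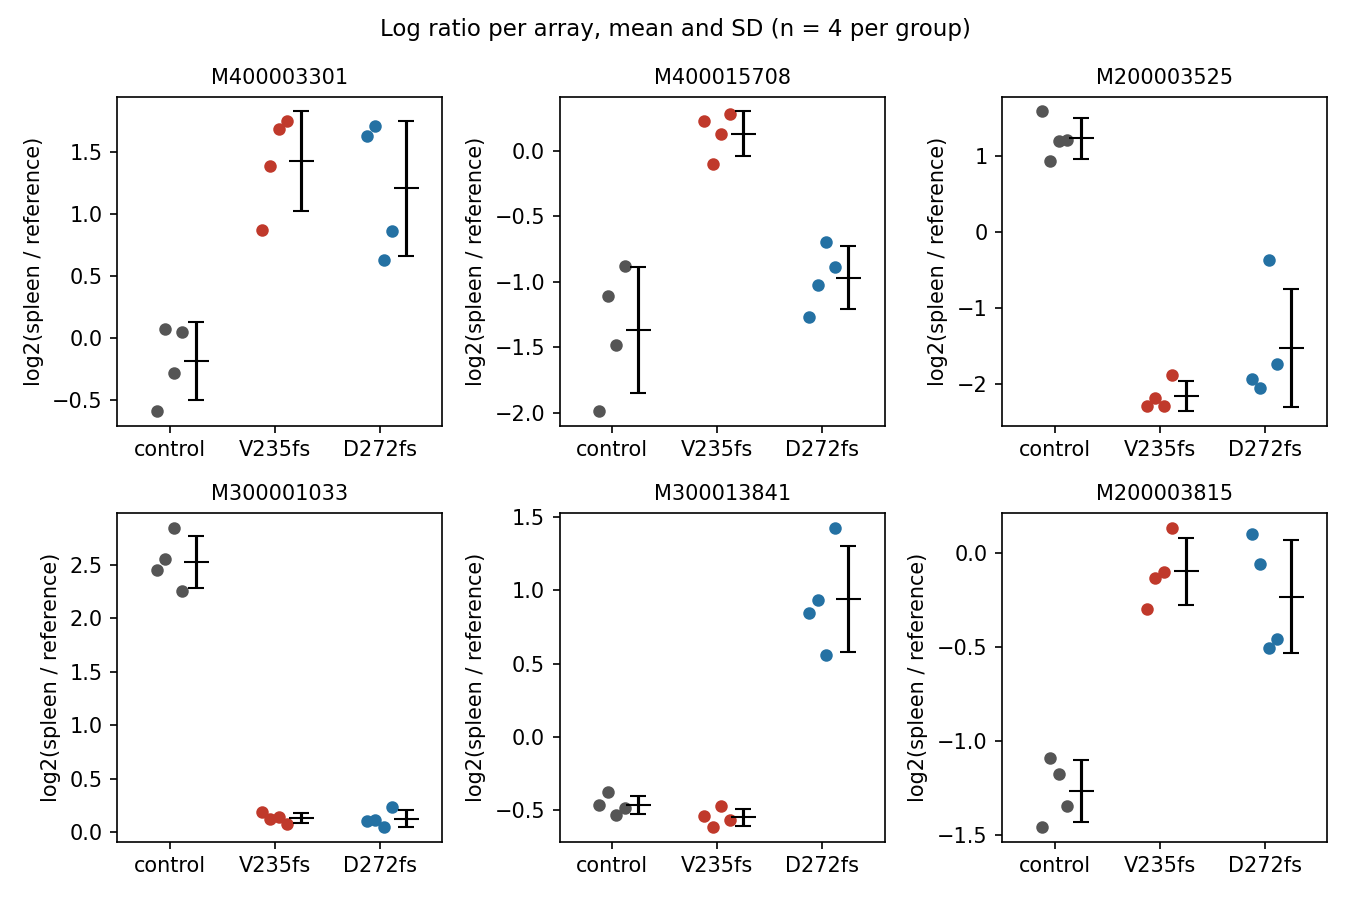
Log2 ratio of spleen over reference (vertical axes) for the 6 named probes in control, V235fs and D272fs; points are single arrays and bars are the mean and SD of 4. M200003525 averages 1.23 in control and −2.16 in V235fs, and M300013841 averages 0.94 in D272fs and −0.46 in control.

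The second comparison asked how the D272fs spleen differed from control. The change reached 20 probes, 9 upwards and 11 downwards, and 6 of them at least 2-fold. M200003525 and M300001033 fell here as well: M200003525 stood at −1.53 ± 0.78 (SD, n = 4), 6.75-fold below control (log2 change −2.75, SE 0.31, limma adjusted p = 0.00988), and M300001033 at 0.13 ± 0.08 (limma adjusted p = 1.79e-06). The measured log2 change of M300001033, −2.40, is uncertain because only 1 of 4 D272fs arrays had it well above background, and that of M200003525 was between −4.81 and −2.58 under the alternatives. M300013841 rose from −0.46 ± 0.06 to 0.94 ± 0.36 (SD, n = 4 each; log2 change 1.40, SE 0.14, limma adjusted p = 0.00481). M200003815 rose from −1.27 ± 0.17 to −0.23 ± 0.30 (log2 change 1.03, SE 0.15, limma adjusted p = 0.0372).

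In this comparison all 20 called probes were without overlap between the groups, as were 8.02% of tested probes, where chance gives 2.86%. The count was 100 without D272fs replicate 3 (75 up, 25 down), 217 with a background from negative control spots (147 up, 70 down), 5 with slide or scan day as a random block and 7 with position as a fixed block, and each of these blocks ended the call of M200003815, whose change stayed between 1.03 and 1.07 (SE 0.16 to 0.19). Scale normalisation gave M200003815 a change of 0.26 (SE 0.53). It was 3 without D272fs replicate 1, 5 or 6 without V235fs replicates 2 to 4 or D272fs replicates 2 or 4, and 8 or 9 without control replicates 1 to 3. Rises were more numerous without background subtraction (149 of 208) and without control replicate 4 (16 of 19) as well, while median centring called 0 rises and 3 falls. All 20 probes kept their call without D272fs replicate 3, but only 16 did with a background from negative control spots, 15 without background subtraction and 14 with Agilent's processed log ratios, although more probes were called in each; all 20 kept their sign.

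Direct comparison of the mutations called 1 probe. M300013841 was lower in V235fs, at −0.55 ± 0.06, than in D272fs, at 0.94 ± 0.36 (SD, n = 4 each), a log2 difference of −1.49 (SE 0.14, limma adjusted p = 0.00777). An unadjusted p under 0.05 was reached by 3145 probes and 7.10% of tested probes were without overlap, where chance gives 2.86%. The count was 371 without D272fs replicate 3, 24 with a background from negative control spots and 12 with position as a fixed block. It was 0 without V235fs replicate 1, 2 or 4 or D272fs replicate 2, which ended the limma call (difference −1.49 to −1.47, adjusted p 0.0525 to 0.0631) while 1883 to 3568 probes reached an unadjusted p under 0.05, and 3 without control replicate 4.

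The last comparison asked how alike the changes of both knock-ins were. Of the called probes, 17 were shared, 8 higher and 9 lower in both and 0 in opposite directions. Independent lists would share 0.045 and 0.040, which leaves the shared controls out of account. Simulated unchanged arrays, in which both knock-in groups had the same simulated controls, shared 0.02 on average. Unchanged arrays give few calls, so that figure does not show what lists of the real length would share through common controls. Neither figure is therefore a baseline for the 17. The probes called in V235fs had a median change of 0.66 in their direction there and 0.39 in D272fs. Of these, 226 of 228 (99.1%) had the same sign. In the simulations 92.1% (86.4% to 95.6%) of the 228 probes with the smallest V235fs p, called or not, had the same sign. Across all tested probes, which are not independent, the changes correlated at 0.613, against 0.50 (0.480 to 0.526) in the simulations. Their covariance was 0.0466 against 0.0141, a difference of 0.0326. With the controls split 2 and 2 the correlation was between 0.211 and 0.575. All 8 knock-in arrays shared a scan day with no control array, which neither the simulations nor the split controls take into account. The number of shared probes was 58 without D272fs replicate 3, 167 with a background from negative control spots and 4 with slide, scan day or position as a block. It was between 2 and 8 without any 1 of 9 other arrays (V235fs replicates 2 to 4, D272fs replicates 1, 2 and 4, control replicates 1 to 3) and 17 without V235fs replicate 1 or control replicate 4.

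**Figure D3:**
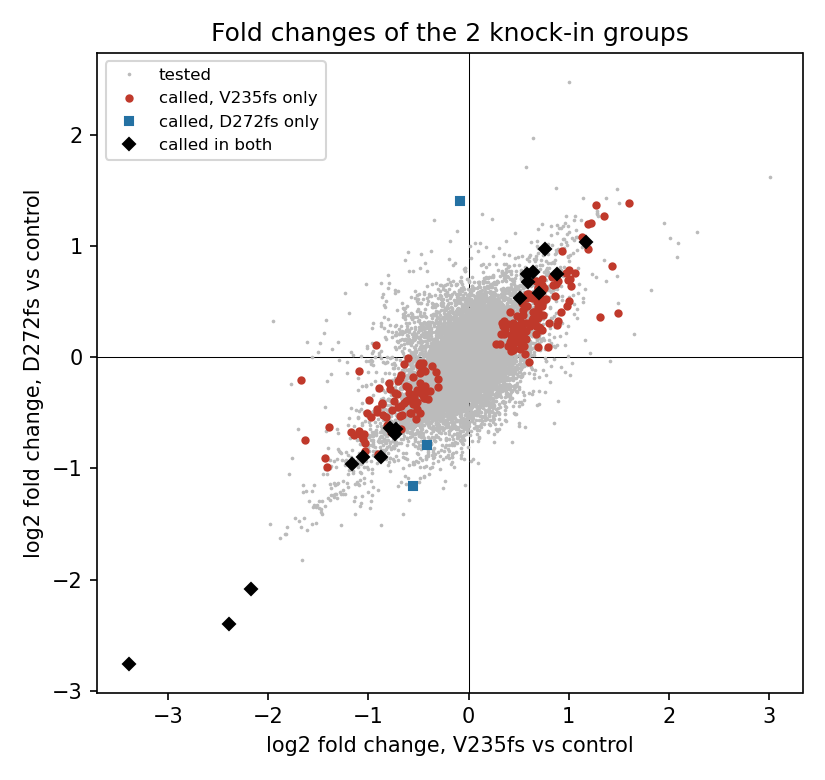
Log2 fold change against control of each tested probe in V235fs (horizontal axis) and D272fs (vertical axis), with called probes coloured by the comparison that called them. The 17 probes called in both lie in the lower left (9) or upper right (8), and M300013841 stands alone at 1.40 in D272fs.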

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

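The tests of background, reference, slide and scan day in this part were chosen after the results were seen; the counts of other splits follow a fixed procedure, but what they would show was also written down only afterwards.

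D272fs replicate 3 stood apart from its group, with a mean correlation of 0.865 against 0.928 to 0.934 for the other 3 arrays. A spleen unlike its group would stand apart under any background, but without background subtraction the correlation was 0.964, within the spread of the others. With a background from negative control spots it was 0.963, so the failed background fit on this array is a likely source of the gap.

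In V235fs, the 10 probes whose translated sequence matched histone H4 had a mean log2 ratio of 0.34 on replicate 1 and between −0.61 and −0.57 on the other 3 arrays. These and the gap of D272fs replicate 3 were the 2 such gaps found in 45 groups of 4 values examined, where chance gives about 1 in 20. Their number is no more than chance would give, and some of the 45 groups overlap. It does not settle the source of either gap, and that of D272fs replicate 3 goes with the failed fit above. V235fs replicate 1 was also the only V235fs array at slide position 4, where control replicates 1, 2 and 4 lay. M300013841 differed between the knock-ins by a log2 value of −1.49.

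The Cy5 channel, which holds the same reference RNA on every array, differed between V235fs and control arrays at 7989 probes when tested alone. Its changes correlated with those of Cy3 at 0.575 across probes, with a root mean square of 0.245 log2 units against 0.342 in Cy3. It differed at 2298 probes between D272fs and control. Between V235fs and D272fs, which shared a scan day but not a slide, it differed at 4507. As the reference RNA is the same, these differences are technical. Scan day cannot account for the 4507, because both knock-in groups shared it, which leaves slide or something that goes with it. In the comparisons with control, slide and scan day cannot be told apart.

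The 228 calls between V235fs and control were weighed against chance, the reference and the background. Only 1 of the 35 splits of the 8 arrays, the real one, gave as many calls, and the highest other gave 0. The calls therefore follow the real grouping, which is also a grouping by slide and scan day. Every other split mixes knock-in and control slides and days within a group, which widens the spread and favours a count of 0. Chance cannot be excluded on this ground. The reference contributed a median of 0.11 log2 units (0.106) to a median change of 0.66, with an upper quartile of 0.28. At 46 of the 228 probes (20.2%) it contributed more than the spleen channel did. The reference does not account for these calls as a set, but holds the larger part of the change at those 46. D272fs replicate 3, where the background fit failed, is in neither group and adds only to the shared spread. With a background from negative control spots 228 of 228 calls were kept. As 2194 probes were called there, this is a weak test of the poor fit on V235fs replicate 4. Slide and scan day cannot be told apart from genotype, because no slide or day holds both V235fs and control arrays. The controls of different days, 2 against 2, differed at 141 probes. At the same size, 2 V235fs arrays against 2 controls of different days differed at 1 to 32 probes (median 2) in 24 tests. All 24 lay at or below 141, although in these tests the control pair spans both days, which widens its spread. Of the 226 V235fs calls that could be tested between those days, 0 were called there, with a median change of 0.14 (0.137) against 0.66 log2 units. As calling favours probes that vary little within the controls, this excludes neither, and no control array shares the day of the V235fs arrays. The genotype stays open and untested.

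For D272fs against control, 1 of 35 splits, the real one, gave as many as the real 20 calls and the highest other gave 0. For the 17 calls in both comparisons, 1 of 100 regroupings did and the highest other gave 0. Both counts carry the same limit, as the other groupings mix knock-in and control slides and days. Chance was not excluded for V235fs against D272fs either, where 2 of 35 splits gave the real count of 1 and the highest other gave 1.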

How the results depend on the processing

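The settings named as added, and those that combine a background from negative control spots with a block, were chosen after seeing the data. No correlation or named-probe change reversed, but the balance of rises and falls among the calls did: from 132 and 96 to 301 and 409 (without V235fs replicate 1), 48 and 89 (without control replicate 3) or 464 and 547 (only the 2 groups) in V235fs, and from 9 and 11 to 147 and 70 (negative control background), 75 and 25 (without D272fs replicate 3) or 16 and 3 (without control replicate 4) in D272fs. Counts follow the order V235fs against control, D272fs against control, V235fs against D272fs and both knock-ins, from 228, 20, 1 and 17, with the correlation of changes from 0.613. The causes of the movements were not tested unless given.

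Another background moved most values, although Agilent's ratios and the authors' values differ in dye normalisation as well. Agilent's processed log ratios gave 2303, 122, 11 and 106 (correlation 0.690), the authors' rounded values gave 2294, 122, 11 and about 1.1e+02 (0.690), no background subtraction 2816, 208, 29 and 167 (0.673), and an offset of 0 gave 51, 3 and, for both, 2. The added background from negative control spots gave 2194, 217, 24 and 167 (0.674), and leaving out D272fs replicate 3 as well gave 1813, 102, 390 and 61. Normalisation mattered too: scale normalisation gave 14, 7, 0 and 6, median centring 6, 3, 0 and 3 (0.740), and the Cy3 channel alone 4916, 164, 2937 and 122 (0.523). Where limma called 0 probes between V235fs and D272fs, an unadjusted p under 0.05 was reached by 2266 (scale), 1147 (median centring) and 2535 (replicate block); at slide position 4, with 1 D272fs array, 3350 reached it between D272fs and control.

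Slide as a random block gave 50, 5 and, for both, 4, and added scan day as one 26, 5 and 4. Position as a fixed block gave 7, 7, 12 and 4, and added slide position 4 alone 10, 0, 7 and 0 (0.432). That fit holds 1 V235fs, 1 D272fs and 3 control arrays and assumes that the lone arrays vary like the controls, so its calls say little. With the background from negative control spots, V235fs calls were 10 with the slide block, 59 with the scan day block and 15 with the position block. The replicate block gave 15, 2, 0 and 2; the deviations of same-numbered arrays correlated between −0.515 and 0.351, above 0.1 in 3 of 12 pairs, so the numbers were not taken to pair the samples. In both knock-in groups the number follows the position on the slide.

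Array weights gave 7640, 3356, 1778 and 2254, a variance trend with robust moderation 480, 60, 2 and 46, and fits with only the groups compared 1011, 2 and 4. An adjusted p under 0.01 left 17 and 4 calls and a change of at least 2-fold 36 and 6, as stricter limits must. Leaving out each array gave 17 to 1398, 3 to 100, 0 to 371 and 2 to 58, with correlations of 0.527 to 0.652; the highest counts came without D272fs replicate 3. The filters on dim probes and marked spots kept every count within 1.5 times. Aquantile leaves log ratios as they are, so its equal values carry no information.

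Leaving aside Aquantile and slide position 4, M200003525 and M300001033 kept their V235fs calls in 31 of 31 and 30 of 30 alternatives (adjusted p up to 0.0165 and 0.0111), and in D272fs lost them in 4 and 2. M400003301 lost its call in 13 of 31, M400015708 in 6, M200003815 in 18, and M300013841 in 4 against control and 8 against V235fs, with no change of sign. Choosing 1 probe per gene was not run, because the probes carry no gene names. Probes well above background in Cy3 were 69.2% to 74.9% per array, which limits what dim probes can show.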

Other observations

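All tests in this part, and the protein sequences behind them, were chosen after the fold changes were seen, so each reading is a hypothesis. Gene identities below come from translating the probe sequences, not from the files.

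M200003525, which fell in both knock-ins, has the sequence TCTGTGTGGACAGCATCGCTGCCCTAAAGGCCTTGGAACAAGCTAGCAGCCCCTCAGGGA. In 1 frame it encodes 19 residues, of which 16 are identical to human TREX1 from residue 152 onwards; the next best of 26502 tested probes and the best match to the reversed protein each had 10. The probe may therefore read mouse Trex1, and its fall may reflect replacement of the mouse gene by the human one, which was not tested and depends on the control genotype, which the labels do not give. With a background from negative control spots it was 12.4-fold below control in V235fs and 9.54-fold below in D272fs, and D272fs replicate 3 moved from −0.38 to −1.99. Agilent's processed log ratios, which differ in dye normalisation as well, put it 40.0-fold and 28.1-fold below control. With an offset of 0 its log2 change in V235fs was −4.52, against −3.39 with the main setting. The size of the fall therefore depends on the processing, the background included.

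Probes that matched core histones (at least 12 residues identical) numbered 44, and 16 of them were among the 96 probes lower in V235fs (16.7%, against 0.166% of tested probes; Fisher's exact test p = 9.04e-29, which is too small because histone probes share sequence). Histones package DNA, and most core histone transcripts are made during S phase. All 8 H2B probes, 6 of 10 H4 and 2 of 15 H3 probes were called lower in V235fs, and 0 of 11 H2A probes were. Over all probes, only 5 were called lower in V235fs with position as a fixed block and 12 with scan day as a random block. Most of these 16 histone calls were therefore lost with position. With scan day the 12 included M200003525 and M300001033, which are not histone probes. How many histone probes were among the 12 was not counted, but at least some of the 16 calls were lost there too. The median change over the 44 was −0.68 in V235fs and −0.20 in D272fs. In D272fs, 4 H4 probes were called lower, and the median of H2A was 0.31 there, but −0.57 with median centring, which moved the median of all probes to −0.24 in D272fs and −0.14 in V235fs. As a set the 44 were lower in V235fs than in control (camera with an estimated correlation, p = 0.00719, adjusted p = 0.0434), and than in D272fs (adjusted p = 0.0434). For D272fs against control the adjusted p was 0.340. Of the 44, 38 were lower in V235fs than in control, with 10 of 15 H3 and 10 of 11 H2A probes among them. By family, camera gave V235fs against control an adjusted p of 0.0434 for H4 and for H2B, 0.135 for H3 and 0.298 for H2A. The set result therefore rests mostly on H4 and H2B. The per-array means of the 44 differed by −0.65 between V235fs and control, and by −0.21 between D272fs and control, each with an exact two-sided permutation p = 0.0286 (n = 4 each; the smallest these can give).

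Of the technical explanations for the lower histone probes, only the reference, position, slide and scan day were weighed. The reference contributed a median of 0.0894 of 0.68 log2 units, so it does not explain the fall as a whole. With position on the slide as a block the median was −0.45 (−0.451). Position was uneven between the groups: control replicates 1, 2 and 4 lay at position 4, as did only replicate 1 of V235fs. There the mean of the 44 was 0.06 on V235fs replicate 1 and 0.27, 0.36 and 0.39 on those controls. At position 1 it was −0.34 on V235fs replicate 4 and 0.32 on control replicate 3. Position may therefore carry part of the fall. With other settings the median change was between −1.05 and −0.45, and without any 1 array between −0.81 and −0.58. In D272fs other settings gave −0.78 to −0.11. Slide and scan day cannot be told apart from genotype: the controls of the 2 days differed by a median of 0.07 (0.0690), but with H4 at 0.32 and H2A at −0.59. A lower share of cycling spleen cells is a candidate explanation that was not tested. The mean log2 ratio of the 44 was 0.06 on V235fs replicate 1, between −0.50 and −0.34 on the other 3, and between 0.27 and 0.39 in control.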
